A study of Homo sapiens with 4 samples.

How the data were processed

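RNA from exosomes, small vesicles released into the culture medium, was measured on 4 one-colour Agilent arrays. The exosomes came from SKOV-3, an established human ovarian carcinoma cell line. Per the labels, cells growing in RPMI1640 with 10% serum were washed and seeded at 1000000 cells per dish in medium with exosome-depleted serum. The cells were kept at 37 °C under 2% oxygen (hypoxia) or 5% oxygen (normal). Each group is labelled with 90% nitrogen and 5% carbon dioxide, so the gas shares given for hypoxia do not add up to the whole. The labels' protocols and source names give 72 h of culture, while the sample descriptions give 24 h, and the sources do not settle which holds. Exosomes were collected with a kit for total exosome isolation, and 1 µg of total RNA was labelled with Cy3, per the labels' protocols.

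The deposited scanner files hold intensity values per spot. Per the file headers, the authors extracted them with Agilent Feature Extraction 11.0.1.1. The submitters' processing notes name Agilent Feature Extraction 10.7.1.1. The processed signal in these files is background-subtracted and detrended, carries a surrogate value for dim spots and is not normalized between arrays, per the file headers and column names. The series' value table holds log2 values deposited by the authors for 58944 probes, with column medians between 3.08 and 3.081. How it was made is not given in the sources used here. Its columns correlated at 0.994 (Pearson) with log2 processed signals that were quantile normalized for the comparison, and each column ranked probes most like its own array (Spearman 0.952 to 0.965, against at most 0.904 for another array). It was used as an alternative.

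Each array held 61184 listed spots: 58945 gene probes of 1 spot each, 1439 control spots, and 800 further spots of custom probes and of probes labelled as negative. The gene probes carry manufacturer identifiers only. None of the identifiers (0 of 58945) was found in the RefSeq gene table at hand, and the files do not pair them with genes. The 21 gene lists fixed before the data were examined (hypoxia-inducible factor targets, lncRNAs, markers of other cell types and others), the comparison of lncRNAs with mRNAs and the naming of genes by class were therefore not analysed here: 0 of the 21 lists could be tested. Genomic positions were likewise not analysed here. Apart from control probes labelled E1A, the only gene names in the files are GAPDH and PGK1, in the names of 12 control probes.

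Gene probe signals were converted to log2, and each array's 75th percentile over its gene probes was subtracted. Outlier-flagged spots, 2 to 7 per array, were left out. Probes entered the test when their spot was well above background on at least 2 of the 4 arrays, which held for 26326 probes. Of these, 12 with a flagged spot were dropped, which left 26314. Hypoxia was compared with normal by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariate, 2 residual degrees of freedom per probe). P-values were adjusted over all tested probes by Benjamini-Hochberg, with a threshold of 0.05. A second count took probes at least 2-fold apart with an unadjusted p under 0.05. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

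The rule for named features, fixed before the data were examined, took probes past the adjusted threshold by size. Where too few passed, it was filled by the smallest unadjusted p among probes at least 2-fold apart with non-overlapping arrays. Because no probe could be named, it was applied to identifiers and limited to 2 probes per direction. The rule also named GAPDH, ACTB, MALAT1, NEAT1 and ERBB2 in every case. Of these, only GAPDH appears in the files, and the control probes named for it stand in for it. PGK1 is on the list of hypoxia-inducible factor targets, from which the rule took only the members with the smallest p. That list could not be tested, so PGK1 was not named by the rule. It is reported because control probes carry its name. Spots of a control probe were averaged on each array, and groups were compared by an exact permutation test with 6 arrangements, whose smallest two-sided p is 0.33. Where a probe was not well above background on either array of a group, a fold is given as a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among gene probes well above background. For control probes, the same was done where 50% of the spots or fewer were well above background on both arrays of a group.

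The test was checked on simulated data: 26314 probes with the real mean signals, spreads drawn from the fitted prior (1.68 degrees of freedom, SD 0.286 on the log2 scale) and 200 changed probes. For the comparison of hypoxia with normal, 0% of simulated 2-fold and 0% of simulated 4-fold changes passed the adjusted threshold, as did 38% of 16-fold and 76% of 256-fold changes. Of the unchanged simulated probes, 4.93% had an unadjusted p under 0.05. The adjusted threshold was passed by 7 of 26114 unchanged probes, beside 19 probes changed 16-fold and 38 changed 256-fold. In the real comparison, the share of unchanged probes was estimated from the p-values at 70.9%, far lower than in the simulation. The adjusted threshold is easier to pass when more probes change, so the simulated rates need not hold for the real comparison.

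All 4 headers record 1 scan of 1 slide, so slide and scan could not be used as a block. The array positions recorded in the headers place both hypoxia arrays together and both normal arrays together, so array position and group cannot be told apart. Alternatives were quantile normalization, median scaling, a 75th percentile over the probes well above background on all arrays, no filter and a stricter filter on dim probes, the authors' value table, eBayes with trend and robust options, a replicate block and leaving out each array. Normexp background correction (offset 50) was planned on mean signals. The files give median signals, which were used instead, so this alternative was chosen after seeing the data. Cyclic loess and raising dim values to the lowest well-above-background signal were also chosen after seeing the data.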

Results

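The study compared exosomal RNA of SKOV-3 cells held under 2% oxygen with that of cells held under 5% oxygen, with the aim, as its title states, of finding exosomal lncRNAs that differ between the conditions. There were 2 arrays for each group, numbered 1 and 2 in the labels. On hypoxia replicates 1 and 2, 26131 and 25380 of the 58945 gene probes were well above background. On normal replicates 1 and 2, the numbers were 23975 and 26197. No gene probe was saturated (0 on each array). The file headers record a median coefficient of variation of 23.8 for hypoxia replicate 1 and 13.1 for hypoxia replicate 2. For normal replicates 1 and 2 they record 12.6 and 11.2. The 75th percentile of the gene probe signal was 61.7 and 59.6 units on the hypoxia arrays and 55.1 and 67.0 units on the normal arrays. The share of gene probes well above background was 43.7% ± 0.901 (SD, n = 2) under hypoxia and 42.6% ± 2.67 (SD, n = 2) under normal oxygen. The difference of 1.14 points was above the SD of the hypoxia replicates and below that of the normal replicates, and the groups overlapped (exact permutation test, two-sided p = 1, smallest possible 0.33).

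Arrays of one group resembled each other more than arrays of different groups. The median probe differed by 0.30 on the log2 scale between the 2 hypoxia arrays and by 0.36 between the 2 normal arrays. Between a hypoxia and a normal array, the median difference ranged from 0.44 to 0.55. Pearson correlations across the 26314 tested probes, which are not independent replicates, were 0.925 within hypoxia, 0.917 within normal and 0.897 to 0.910 across groups. Differences of at least 2-fold separated 12.8% of probes between the hypoxia replicates and 18.6% between the normal replicates. Across groups, 22.5% to 27.2% of probes differed by that much.

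Between hypoxia and normal, most exosomal transcripts lay close together and a minority lay far apart. Group means were within 1.5-fold for 62.2% of the tested probes, at least 2-fold apart for 5112 (19.4%), at least 4-fold apart for 1146 (4.36%) and at least 8-fold apart for 310 (1.18%). Among the 4127 probes that were at least 2-fold apart with no overlap between the arrays of the groups, 2369 were higher and 1758 lower under hypoxia. Of 266 such probes at least 8-fold apart, 63 were higher and 203 lower. The balance at 2-fold depended on the processing. Median scaling gave 1681 higher and 2316 lower (45 and 247 at 8-fold). Normexp background correction on the median signal gave 703 and 895. The 2-fold count was 6482 without normal replicate 2 and 6667 without the filter on dim probes. The 8-fold count was 124 among probes well above background on all 4 arrays and 50 with normexp. Leaving out any one array, which makes non-overlap easier to reach, gave 446 to 640. Non-overlapping arrays were seen for 53.6% of all tested probes, where chance gives 33.3% on average for 2 arrays against 2. The other 2 ways of parting the arrays gave 21.44% and 24.95%. Each probe falls in 1 of these 3 ways, so 1 of the shares must reach 33.3% in any data. The excess therefore cannot be told from chance. Non-overlap also occurred outside the gene probes: of 145 control, custom and negative probe names, 34 were higher and 34 lower under hypoxia without overlap. Some of these names gave nearly the same signals as each other, so they are not independent.

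No probe passed an adjusted p of 0.05 in limma's moderated test (0 higher, 0 lower). The lowest adjusted p was 0.0826. At an unadjusted p under 0.05, the test counted 4340 probes (16.5% of those tested, where 5% would arise by chance), 2570 higher and 1770 lower under hypoxia. This count was 2375 without hypoxia replicate 2, 2582 without hypoxia replicate 1 and 6519 without the filter on dim probes. Without that filter 58928 probes were tested, so the share was lower, at 11.1%. With the trend and robust options of eBayes, 1 probe passed the adjusted threshold and 4283 the unadjusted one. Of the probes with an unadjusted p under 0.05, 2859 were also at least 2-fold apart, and of these 57.5% (1643) were higher and 1216 lower under hypoxia. This split depended on the processing. Median scaling, which set the median probe at -0.15 instead of 0.01 on the log2 scale, gave 41.0% higher. Normexp, which changed signal column, background correction and offset together, gave 45.3%. Both criteria were met by 4367 probes without normal replicate 2, by 4618 without the filter on dim probes and by 1044 with normexp.

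**Figure D1:**
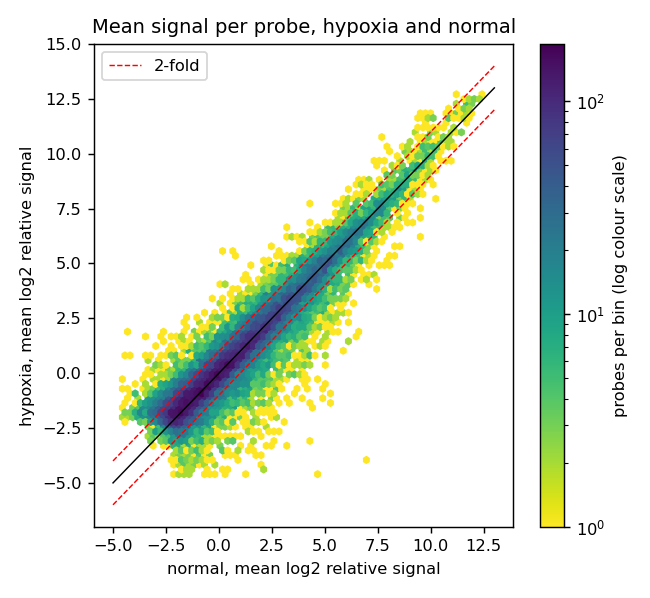
Mean log2 signal of each of the 26314 tested probes, relative to the 75th percentile of its array, on the 2 normal arrays (horizontal axis) and the 2 hypoxia arrays (vertical axis); the colour gives the number of probes per bin on a log scale, the solid line marks equal means and the dashed lines 2-fold differences. Group means of 5112 probes lay outside the dashed lines.

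The probe with the smallest p, ASHGA5P002370, was bright on both normal arrays (4.70 ± 0.0601 on the relative log2 scale, SD, n = 2) and not well above background on either hypoxia array (-4.55 ± 0.067, SD, n = 2). Its signal was at least 132-fold lower under hypoxia (limma, adjusted p = 0.0826). ASHGA5P056531 had the same pattern, at 2.10 ± 0.187 under normal oxygen and -4.48 ± 0.0526 under hypoxia (SD, n = 2), at least 21.8-fold lower under hypoxia (limma, adjusted p = 0.203). In the opposite direction, ASHGA5P017986 was at 0.83 ± 0.505 under hypoxia and was not well above background on either normal array, at -4.44 ± 0.231 (SD, n = 2). It was at least 8.43-fold higher under hypoxia (limma, adjusted p = 0.213). ASHGA5P010537 stood at -1.17 ± 0.076 under hypoxia against -4.25 ± 0.164 under normal oxygen (SD, n = 2), at least 2.12-fold higher (limma, adjusted p = 0.213). These bounds hold for the processed signal: with normexp, which changed the signal column and the background correction and added an offset of 50, the log2 folds were -4.76 for ASHGA5P002370, -2.40 for ASHGA5P056531, 1.42 for ASHGA5P017986 and 0.44 for ASHGA5P010537, all smaller in size than the bounds. None of these 4 probes passed the threshold in this fit, and no gene name or position is known for them here.

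Detection itself differed between groups for some transcripts. There were 692 gene probes well above background on both hypoxia arrays and on neither normal array, and 446 with the reverse pattern. Together these made 1138 probes. The same count was 518 when both replicates 1 were set against both replicates 2, and 605 for the remaining pairing of the arrays. On all 4 arrays, 21628 gene probes were well above background, and on no array 29281.

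The 4 arrays can be parted 2 against 2 in 3 ways. An unadjusted p under 0.05 was reached by 4340 probes for hypoxia against normal, by 677 for replicate 1 against replicate 2 and by 732 for the crossed pairs (limma in each case, 0 probes past the adjusted threshold in each direction). The first of these counts was 2375 and 2582 without hypoxia replicates 2 and 1, and 6519 without the filter on dim probes. The count without the filter was 11.1% of the 58928 probes then tested. In the other splits, any difference between the oxygen groups counts as spread within pairs, which lowers their counts of small p-values. Those splits reached 2.57% and 2.78% of the tested probes, below the 5% that would arise by chance, so they overstate the contrast. Probes at least 8-fold apart with non-overlapping arrays numbered 266, 348 and 234 for the 3 splits in the same order. Differences of this size were therefore no more frequent between oxygen levels than between the replicate numbers. At 2-fold without overlap, the counts were 4127, 1566 and 1591 in the same order, highest for oxygen. A probe without overlap in 1 split cannot be so in another, so the counts of the 3 splits are not independent.

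**Figure D2:**
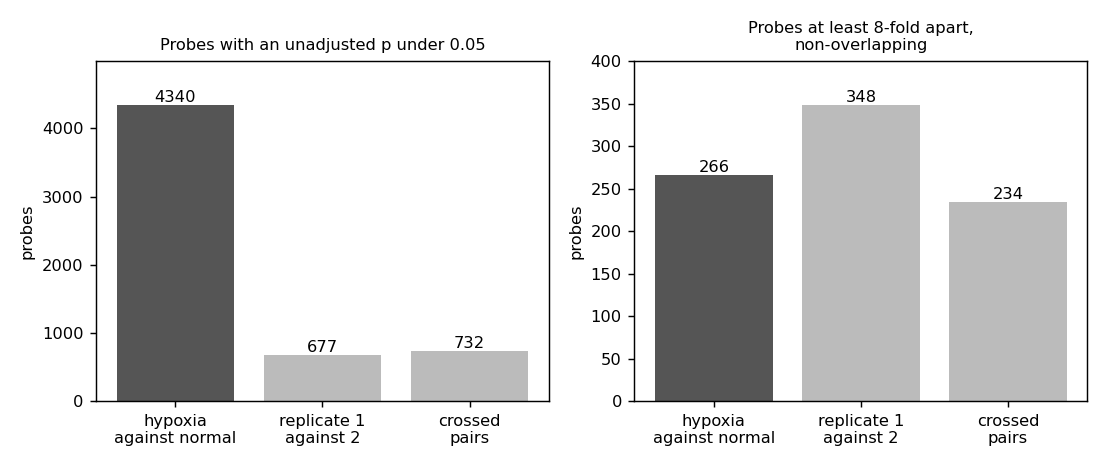
Number of tested probes (vertical axes, from 0) for the 3 ways of parting the 4 arrays 2 against 2, with an unadjusted p under 0.05 (left) and at least 8-fold apart with non-overlapping arrays (right). The split by oxygen gives 4340 probes on the left against 677 and 732, and on the right 266 against 348 and 234. On the left, a difference between the oxygen groups lowers the counts of the other splits.

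GAPDH and PGK1 are glycolytic enzymes whose mRNAs are known targets of the hypoxia response. Here the RNA came from exosomes and the comparison was 2% against 5% oxygen, so that response of the cells was not tested. The arrays carry 12 control probes named for GAPDH or PGK1 and for human, mouse or rat, each on 10 spots. Of these, 6 were well above background on most of their spots on every array. Neither gene was uniformly higher under hypoxia by these probes. The probe Human-PGK1_3 gave 7.52 ± 1.70 under hypoxia and 7.79 ± 1.00 under normal oxygen (relative log2 signal, SD, n = 2, exact permutation p = 1). For Human-PGK1_3, replicate 1 exceeded replicate 2 by 5.29-fold under hypoxia and by 2.68-fold under normal oxygen, while the SD among spots of one array was at most 0.195 on the log2 scale. Its sign therefore rested on single arrays, with a difference of 0.93 without hypoxia replicate 2 and of -1.47 without hypoxia replicate 1. Mouse-PGK1_3 was at 0.28 ± 0.366 and 0.73 ± 0.0713 (SD, n = 2), a difference of -0.46 (exact permutation p = 0.33), which was -0.20 without hypoxia replicate 2 and -0.71 without hypoxia replicate 1.

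The GAPDH probes Mouse-GAPDH_5 and Rat-GAPDH_5 had lower values on both hypoxia arrays than on both normal arrays. Mouse-GAPDH_5, the brightest of the 12, was at 10.2 ± 0.167 under hypoxia and 10.9 ± 0.102 under normal oxygen (SD, n = 2), 1.61-fold lower. Rat-GAPDH_5 was at 3.40 ± 0.140 and 4.34 ± 0.0503 (SD, n = 2), 1.92-fold lower. Both gave an exact permutation p of 0.33, the smallest that 2 arrays against 2 allow. Human-GAPDH_5 differed by 0.11 and Rat-GAPDH_3 by 0.01 on the log2 scale, within the replicate spread; median scaling turned them to -0.06 and -0.16, and leaving out single arrays also changed their sign. The probe sequences were not used here, so which transcript region or species each control probe detects rests on its name alone.

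**Figure D3:**
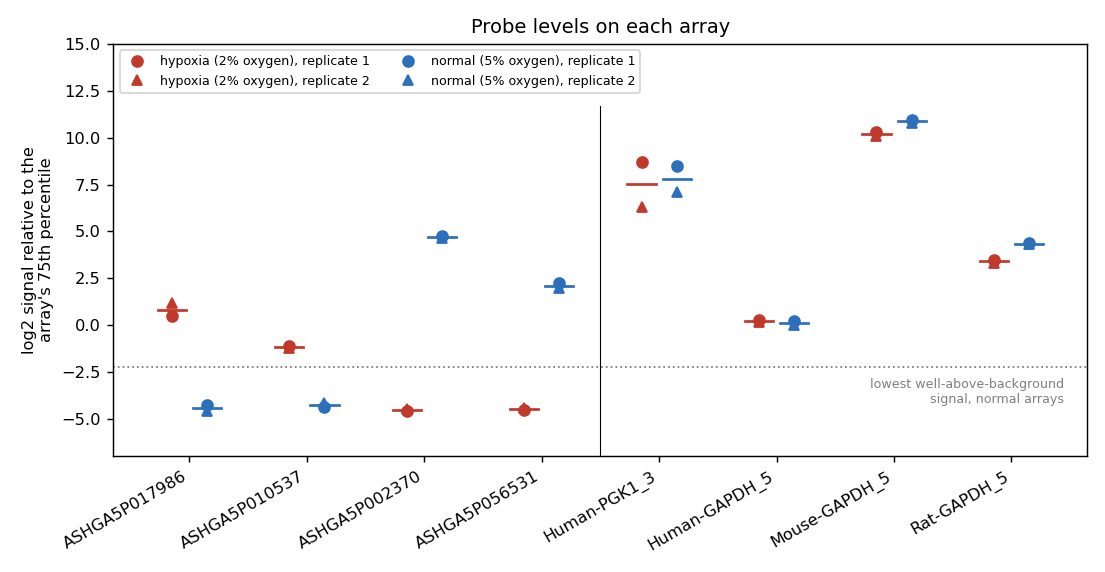
Log2 signal relative to the 75th percentile of each array (vertical axis) for the 4 named gene probes and, right of the vertical line, 4 control probes named for PGK1 and GAPDH; circles are replicate 1, triangles replicate 2, horizontal bars group means, and the dotted line the lowest well-above-background signal averaged over the normal arrays. The named gene probes lie below that line in one group on both arrays, while the replicates of Human-PGK1_3 lie 5.29-fold and 2.68-fold apart.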

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

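The tests of regrouped arrays, of background and of median scaling on the trend with brightness were chosen after the result was seen (median scaling of the counts was planned); those of neighbouring spots, of dim values, of cyclic loess and of leaving out arrays were set down before their results were computed.

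Outside the gene probes, 145 control, custom and negative probe names were examined. Of these, 34 were higher and 34 lower on both hypoxia arrays than on both normal arrays, where chance gives 33.3% in all. Non-overlap, seen for 53.6% of the tested gene probes, thus also occurred outside them. The names are not independent, so their share cannot be weighed against 33.3%. For example, (+)E1A_r60_a22 and DCP_22_0 had nearly the same means (4.034 and 4.035 under hypoxia, 4.279 and 4.288 under normal oxygen). Among the 34 higher probe names, 7 met 2 further criteria. They were well above background on most spots of both hypoxia arrays, and their measured means were at least 2-fold higher than on the normal arrays. Other names detected on most spots of both hypoxia arrays rose by less, such as CUST_14_PI418767722 with 0.47 on the log2 scale. For 4 of the 7 the normal signal was not well above background on most spots of either array, so only a bound can be given. CUST_9_PI418767722, CUST_13_PI418767722 and Negative059, which is labelled as negative, were measured in both groups and higher by 2.23, 1.72 and 1.07 on the log2 scale. CUST_13_PI418767722 was bright on every array (8.10 ± 0.548 against 6.38 ± 0.362, SD, n = 2, exact permutation p = 0.33). For CUST_9_PI418767722 the hypoxia replicates themselves differed 2.98-fold. Of the 4 with a bound, Negative014 was at least 2.07-fold higher, DCP_1_0 at least 1.80-fold, (+)E1A_r60_1 at least 1.54-fold and CUST_8_PI418767722 at least 1.25-fold; their measured log2 means differed by 1.40, 1.37, 1.45 and 1.103, sizes that rest in part on values below background. By the mirrored criteria 3 were lower under hypoxia. Negative046 was measured in both groups, with a log2 difference (hypoxia minus normal) of -2.002, while its normal replicates themselves differed 2.3-fold. Negative047 was at least 5.77-fold and ETG09_35454 at least 1.95-fold lower, neither being well above background on most spots of either hypoxia array. The normal replicates of Negative047 differed widely (0.18 ± 2.06, SD, n = 2). What these probes detect is not known here beyond the labels in their names.

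The count of small p-values was set against the other ways of parting the 4 arrays into pairs. With an unadjusted p under 0.05, 4340 probes parted hypoxia from normal, against 677 for replicate 1 against replicate 2 and 732 for the crossed pairs. The count was 2375 without hypoxia replicate 2, 2582 without hypoxia replicate 1 and 6519 without the filter on dim probes. The count without the filter was 11.1% of the 58928 probes then tested, against 16.5% with it. The real split was thus 1 of the 3 splits with as many probes, and the highest of the others had 732. A share under 0.05 cannot be reached with 3 splits. The others are also no fair reference, since a difference between the oxygen groups counts as spread within their pairs. Their counts were 2.57% and 2.78% of the tested probes, below the 5% that would arise by chance. The position of the arrays on the slide follows the groups, so position and oxygen cannot be told apart. No biological explanation was tested separately.

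Probes at least 8-fold apart with non-overlapping arrays gave another picture. There were 266 between hypoxia and normal, 348 between replicates 1 and 2 and 234 for the crossed pairs. Thus 2 of the 3 splits had as many, with 348 as the highest of the others. At 2-fold without overlap, the counts were 4127, 1566 and 1591 in the same order. A probe without overlap in 1 split cannot be so in another, and 3 splits are too few for a share under 0.05. Disturbed areas of an array are argued against as the source of most of the 266 probes. The spots next to them moved by a median of -0.0138 in the probe's direction (log2). A disturbance behind a minority of them would not show in a median and stays open. Stretching of folds by the surrogate values of dim spots is argued against as the whole source. When dim values were raised to the lowest well-above-background signal, 88.0% stayed at least 4-fold and 71.4% at least 8-fold apart. Part of the size of the folds does rest on those values, as the 8-fold count was 191 under that setting. A candidate explanation that stays open is variation between single exosome preparations, which may bring large differences between any 2 arrays; each probe has 1 spot, so spot-level faults also stay open.

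Dim probes tended to be higher and bright probes lower under hypoxia. The median log2 fold was 0.23 in the dimmest 10% of tested probes and -0.06 in the brightest 10%, a difference of 0.29, which median scaling leaves at 0.29 by construction. More unremoved background on the hypoxia arrays is argued against, since the negative control spots differed by 9.72% of the signal this rise would need. That one array sets the trend fits the values. Without normal replicate 1, the array with the fewest probes well above background, the difference was -0.02 (-6.69% of its size). It was 0.22 to 0.59 without any one of the others. The median log2 fold of the brightest 10% changed sign, to 0.12 without normal replicate 1 and 0.04 without hypoxia replicate 1. It was -0.21 without normal replicate 2 and -0.11 without hypoxia replicate 2. A curved response between arrays stays open. The difference between the dimmest and the brightest 10% was 0.10 with quantile normalization and with the authors' value table, and 0.09 with normexp. Cyclic loess left 25.4% of the trend and 100% of the 8-fold count. The bound set beforehand for arguing against a curve, over 80% of the 8-fold count left, was met, but it was badly chosen, since that count does not measure the trend and the trend itself is what cyclic loess removes; that test was first dropped after its result was seen and is given here for that reason. The trend may thus belong to normal replicate 1, and an effect of the oxygen level on it was not tested separately.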

How the results depend on the processing

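Of the 15 alternatives, normexp changed the signal column, the background correction and an offset together, and the authors' value table also brought back probes with a flagged spot (26325 tested); normexp, cyclic loess and raised dim values were chosen after seeing the data. No alternative gave a probe higher under hypoxia past the adjusted threshold, and 1 gave a lower one: eBayes with trend and robust options called 1 probe, ASHGA5P002370 (limma, adjusted p = 0.0479, range over its alternatives 0.0479 to 0.55). The lowest adjusted p over the alternatives ranged from 0.0479 to 0.55. The count of probes at least 2-fold apart with an unadjusted p under 0.05, 2859 as reported, was 4618 without the filter on dim probes, where 58928 probes were tested, and 1044 with normexp, whose offset of 50 shrinks the folds of dim probes by construction. Leaving out each array in turn gave 2375 to 4367, the highest without normal replicate 2. The count was 1941 with the stricter filter, where 21617 probes were tested, and 2486 to 2958 under the other settings. The share of these probes that was higher under hypoxia ran from 41.0% with median scaling to 65.0% with the percentile over probes well above background on all arrays, which moved the median probe to 0.12 on the log2 scale. The count of probes at least 8-fold apart was 124 with the stricter filter, 50 with normexp and 446 to 640 with each array left out in turn, where 3 arrays overlap less by construction. The 4 named probes kept their direction in the 14 alternatives that gave them a value, but not their size: with normexp the log2 folds were -4.76 for ASHGA5P002370, -2.40 for ASHGA5P056531, 1.42 for ASHGA5P017986 and 0.44 for ASHGA5P010537, below the sizes given as bounds. With the replicate number as a replicate block, 0 probes passed the adjusted threshold and 2910 the fold and unadjusted p. The number was not treated as a pairing, because the labels do not say what it means. Same-numbered arrays deviated together with a correlation of 0.0329 over probes. The slide block, the averages over probes of a gene, the gene lists and the comparison of lncRNAs with mRNAs were not run, for lack of a second slide or of gene names, nor was normexp on mean signals.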

Other observations

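ETG09_35454, a control probe with 12 spots per array, was detected on 91.7% and 66.7% of its spots on the normal arrays and on 0% on both hypoxia arrays, with a relative log2 signal of -1.38 ± 0.774 against -4.35 ± 0.0792 (SD, n = 2). ETG08_142674, detected on all spots of every array, was at 2.19 ± 0.385 under hypoxia and 3.02 ± 0.618 under normal oxygen (SD, n = 2), with hypoxia replicates 1.46-fold and normal replicates 1.83-fold apart. ETG05_36762 was at 2.26 ± 0.00849 and 1.97 ± 0.0075 (SD, n = 2), 1.22-fold higher under hypoxia. Among the 60 probe names labelled as negative, 9 were detected on most of their spots on every array. These control probes were chosen after their values were seen.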
